A study of Homo sapiens with 2 samples.

How the data were processed

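The series measured messenger RNA in single cells of Nalm-6, a human B-cell precursor acute lymphoblastic leukemia line that was modified to carry a doxycycline-inducible (Tet-On) construct. There were 2 libraries, 1 of cells carrying the ETV6-RUNX1 fusion and 1 of cells carrying luciferase as control (LUC control). Per the labels' protocols, expression was induced with 500 ng/ml doxycycline for 24 h, dead cells were depleted with magnetic beads, and droplet libraries with a cell barcode and a unique molecular identifier (UMI) on each poly-A transcript were made on the 10X system.

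The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, over the same 32738 genes in each library. Per the submitters' processing notes, they were made with Cell Ranger 3.0.2 on genome build hg19. The counting of reads between overlapping or near-identical genes is not given in the sources used here beyond that. Neither a luciferase gene nor the fusion has an entry of its own among the 32738 genes. A gene annotation of hg19 was not used here, so no coordinates are given. GENCODE release 29 was used only for transcript GC content and length and for which genes neighbour each other. A symbol shared by several gene identifiers (95 symbols) was kept apart by its identifier.

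Cells were kept with at least 1000 genes detected and at most 10% of UMIs from mitochondrially encoded genes. This kept 2267 of 2503 barcodes in the ETV6-RUNX1 library and 1870 of 2203 in the control library. Doublets were left in. Scrublet (as run in scanpy 1.11.5, expected rate 0.05) called 10 and 18 of the kept cells, or 0.441% and 0.963%; such a caller has little to work with in a culture of a single cell type, and leaving those cells out was an alternative.

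UMIs were summed over the kept cells of each library and expressed as CPM, each gene's UMIs scaled by the library's summed UMIs. The log2 ratio of ETV6-RUNX1 over control was given with its exact 95% interval for a ratio of a pair of Poisson counts. A gene was taken as measured at 10 CPM or more in at least 1 library, which corresponds to 439 and 428 UMIs. With 1 library per group there is no replicate check, cells are not replicates, and no test was made. Genes were counted by size alone, at a ratio of 1.5-fold or more. Intervals of ratios cover counting error only, with UMIs taken as independent. They leave out the spread between cells of a library, so they are too narrow for genes that vary between cells. They also leave out differences between cultures, inductions and library preparations.

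Before the data were examined, 30 gene lists and the rule for named genes were fixed. Named genes are ETV6 and RUNX1, up to 12 genes with the highest and 12 with the lowest ratio among measured genes at least 1.5-fold different with an interval that excludes no difference, and in each list up to 3 measured members with the largest absolute log2 ratio, whatever its size. A gene that this rule would name is not reported here. Of the listed symbols, 11 did not match a gene name in the matrices. For each list with at least 5 measured members, the median log2 ratio was given with an order-statistic 95% interval over its members, and with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Lists with fewer measured members are given by member.

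Cell-cycle phases were called with scanpy's cell-cycle scoring (score above 0) on cells thinned to 8700 UMIs each, leaving out 224 and 84 shallower cells. Shares of cells have exact (Clopper-Pearson) 95% intervals. Ratios were also computed from the unthinned counts of the cells called in each phase, and as phase-matched ratios, in which the 3 phases have equal weight. Cells were clustered (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5) to look for cells of another type, and ratios within clusters are given where named.

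The ratio and its interval were tested on simulated data, with counts drawn for 5906 measured genes from the control library's means and the real library sizes and with 200 genes shifted by known folds for the comparison of ETV6-RUNX1 with control. The 1.5-fold size was reached by 100% of 50 genes simulated at 2-fold, by 50% of 50 genes simulated at exactly 1.5-fold, by 0% of 50 genes at 1.3-fold and by 0 of 5706 genes with no difference. The 95% intervals held the simulated ratio for 95.0% of genes. The counts were Poisson draws of library sums, the model behind the interval, so these results check the computation only. Spread between cells was not simulated.

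Alternatives planned before the data were examined were no cell filter, a stricter cell filter (2000 genes, 5% mitochondrial), Scrublet-called cells left out, median-of-ratios scaling, edgeR's TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without ribosomal protein and mitochondrial genes, equal weight for each cell, thinned cells, phase-matched ratios, cells called G1 only, floors of 1 and 50 CPM, and sizes of 2-fold and a log2 ratio of 0.32. A trend of the ratios over GC content alone, or over GC content and length (lowess, fraction 0.3, statsmodels), was removed as an alternative added after the data were seen; 99.2% of measured genes had a value. Other steps used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Python 3.11.15.

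For the additional observations, a subpopulation of cells was called from 15 genes higher and 15 genes lower in a TFDP1-expressing cluster than in the main cluster of the control library. Measured genes past the 1.5-fold size between libraries and Y-linked genes were left out of these markers, while genes below 10 CPM in each library were not, and a mixture of 2 normal components was fitted to the log2 ratio of their summed UMIs in the control library. As an alternative added after the data were seen, genes past that size at any level were left out too. Correlation between genes across cells was computed on thinned cells after standardising log counts within each called phase (or each phase and cluster), and compared with 1000 random gene sets of the same size, each member drawn within 150 expression ranks. These sets left out measured genes past the 1.5-fold size, and ranks were of the mean CPM of the libraries.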

Results

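ETV6-RUNX1 (also TEL-AML1) is the fusion of a pair of blood transcription factors found in a common form of childhood B-cell precursor leukemia. The series title places it in the study of arrested B-lymphoid differentiation, and the comparison here was of Nalm-6 cells induced to express the fusion with Nalm-6 cells induced to express luciferase. The ETV6-RUNX1 library held 44311919 UMIs in 2503 barcodes, of which 43941536 UMIs lay in 2267 kept cells (median 19219 UMIs and 3263 genes per cell). The control library held 43315742 UMIs in 2203 barcodes, with 42762188 UMIs in 1870 kept cells (median 22535.5 UMIs and 3618 genes). Mitochondrially encoded genes made up a median of 4.51% and 4.36% of UMIs in kept cells. Barcodes with over 50% mitochondrial UMIs were 6.27% of all barcodes (95% interval 5.35 to 7.29) with ETV6-RUNX1 and 9.31% (8.12 to 10.6) in the control. There was 1 library per construct, so each difference below is between those libraries and has no replicate check.

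The genes that make up the construct were examined as a check of the labels. ETV6 (ENSG00000139083) was higher in the ETV6-RUNX1 library, at 10.2 against 6.95 CPM, a log2 ratio of 0.55 (0.33 to 0.76). RUNX1 (ENSG00000159216) was at 33.8 and 34.0 CPM, a log2 ratio of -0.01 (-0.11 to 0.10). In cells called G1 alone the log2 ratios were -0.04 (-0.67 to 0.59) for ETV6 and -0.31 (-0.60 to -0.02) for RUNX1. The ETV6 value there rests on 48 and 42 UMIs, and its interval holds both 0 and the value over all cells. Whether reads from the 3' end of the construct can be counted for either gene depends on how the construct ends, which the labels do not give, so these values are a weak check.

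LAT2, PTPRCAP and RASGRP2 had the lowest ratios with ETV6-RUNX1. LAT2 (ENSG00000086730), an adaptor of antigen receptor signalling, was 3.48-fold lower, at 16.0 against 55.7 CPM (log2 ratio -1.80, -1.92 to -1.68). PTPRCAP, a protein bound to the CD45 phosphatase, had a log2 ratio of -1.51 (-1.59 to -1.43), and RASGRP2, an exchange factor for Rap GTPases, of -1.43 (-1.52 to -1.34). FAM129C followed at -1.27 (-1.38 to -1.17), the lysosomal ATPase ATP13A2 at -1.15 (-1.40 to -0.92) and the B-cell surface receptor CD72 at -0.998 (-1.17 to -0.82). The GTPase RASD1 (-0.98), TFDP1 (-0.94), a dimer partner of E2F factors, the thrombin receptor F2RL3 (-0.94) and N4BP3 (-0.94) were also among the 12 lowest. The remaining entries among the 12 are uncertain: KB-208E9.1 (-0.92) neighbours IGLL1, and NME1-NME2 (-0.90) is a read-through of NME1 and NME2, so reads can be shared.

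Fewer genes were higher with ETV6-RUNX1, and by less. BCAS4 (ENSG00000124243) had the highest log2 ratio, 0.98 (0.84 to 1.12), at 29.1 against 14.8 CPM. GNG11, a G-protein gamma subunit, had a log2 ratio of 0.86 (0.78 to 0.95) at 74.5 against 40.9 CPM. The surface antigen gene CD99 was at 11.9 against 6.95 CPM (0.78, 0.57 to 0.99). Also higher were KIAA0226L (0.84), KANK2 (0.81), CYB5D2 (0.81), DMWD (0.70, but 0.43 in thinned cells), the lipid transfer protein gene CETP (0.68), NKAIN4 (0.66) and QPRT (0.60), an enzyme of NAD synthesis. Of these, NKAIN4 was short of 1.5-fold in thinned cells (0.53) and QPRT under the stricter cell filter (0.57).

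In all, 11 of 5954 measured genes were at least 1.5-fold higher and 39 at least 1.5-fold lower in the ETV6-RUNX1 library, while 5659 genes had log2 ratios within 0.32 of 0. At 2-fold the counts were 0 and 5. With TMM scaling the split was 17 higher and 32 lower, and it was the same with median-of-ratios scaling and with totals that leave out ribosomal protein and mitochondrial genes. These scalings moved each log2 ratio up by 0.04, 0.04 and 0.05.

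**Figure D1:**
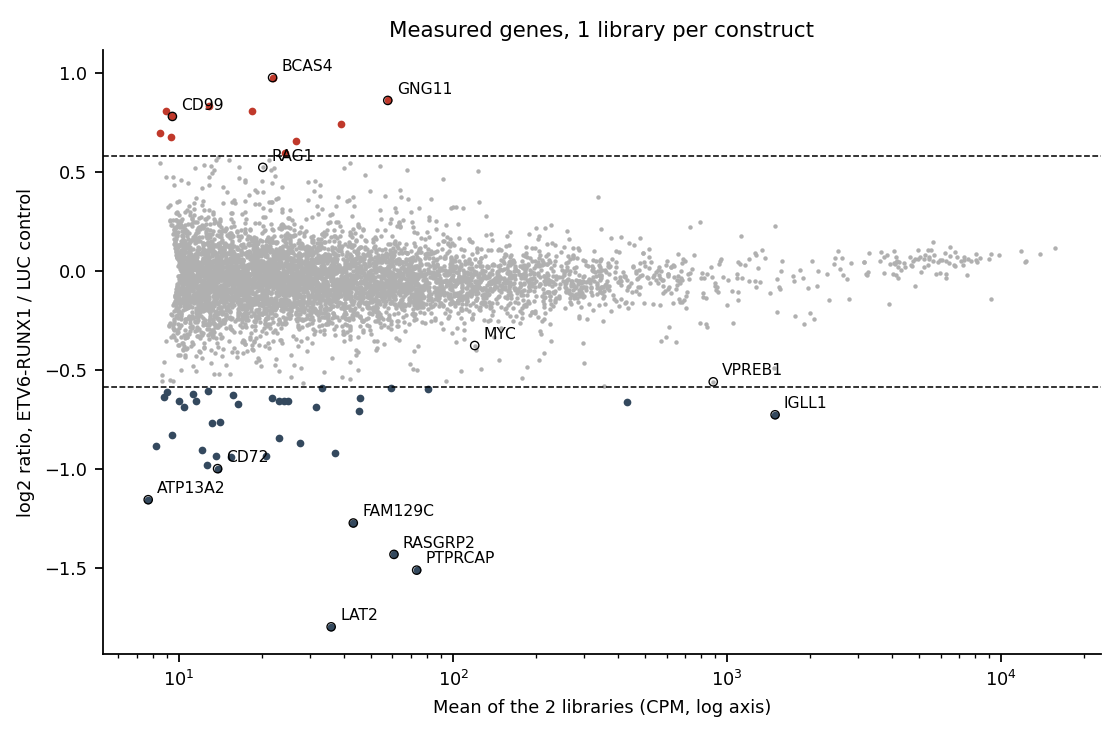
Log2 ratio of ETV6-RUNX1 over LUC control (vertical axis) against the mean CPM of the libraries (horizontal log axis) for the 5954 measured genes, with dashed lines at 1.5-fold, genes past them in red (11 higher) and dark blue (39 lower), and some named genes circled. LAT2, PTPRCAP, RASGRP2 and FAM129C have the lowest ratios, and IGLL1 is the most abundant of the genes past the lines.

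The surrogate light chain genes, which stand in for the immunoglobulin light chain in the pre-B cell receptor, were lower with ETV6-RUNX1. IGLL1 was at 1125.9 against 1861.5 CPM (log2 ratio -0.73, -0.74 to -0.71) and VPREB1 had a log2 ratio of -0.56 (-0.58 to -0.54). Of 18 measured genes of the pre-B cell receptor and proximal signalling, CD72 and IGLL1 were at least 1.5-fold lower and 0 were 1.5-fold higher. The median of this list was -0.08 (-0.39 to 0.10), at percentile 11.7 of matched random lists, so the list as a whole did not stand apart. In cells thinned to the same depth, 10.2% of ETV6-RUNX1 cells (8.90 to 11.6) and 0.840% of control cells (0.471 to 1.38) had no IGLL1 UMI, and the median was 7 against 15 UMIs. Without thinning the shares were 6.66% and 0.588%. This was not particular to IGLL1. In thinned cells with ETV6-RUNX1 and control, 10.3% and 1.01% had no VPREB1 UMI, and 6.51% and 2.24% no MIF UMI. For CD79B the shares were 5.58% and 3.14%, although its means were similar (4.45 and 4.50 UMIs). Within the 5 clusters of cells the IGLL1 log2 ratio was below 0 each time, from -0.17 (-0.20 to -0.14) in cluster 0 to -1.23 (-1.30 to -1.16) in cluster 3. The libraries were spread unevenly over these clusters, which were made with genes that differ between them, so the shares above mix cells of several clusters and cluster sizes were not compared. No cell type that lacks IGLL1 was found in these libraries, so the number of UMIs that free RNA adds per cell could not be set beside these shares.

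**Figure D2:**
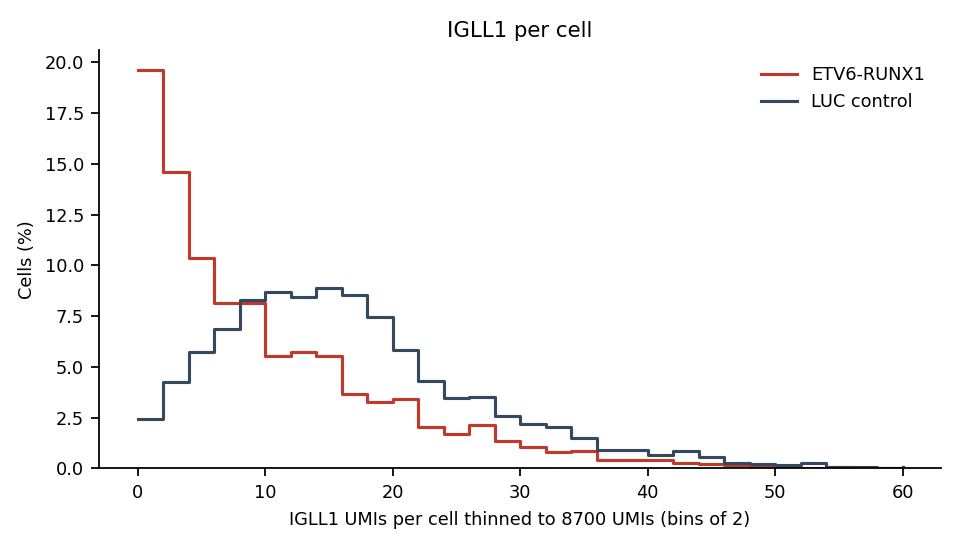
Share of cells (vertical axis, %) by the number of IGLL1 UMIs per cell after thinning each cell to 8700 UMIs (horizontal axis, bins of 2 UMIs), for 2043 ETV6-RUNX1 cells and 1786 control cells. The control cells form a hump around their median of 15, and the ETV6-RUNX1 cells are most frequent in the lowest bin and extend over the same range.

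Other genes of B-cell development went in both directions. The V(D)J recombinase genes RAG1 (0.53, 0.39 to 0.66) and RAG2 (0.22, 0.04 to 0.40; 0.44 in thinned cells) and terminal transferase DNTT (0.21, 0.18 to 0.25) had log2 ratios above 0, but 0 of the 11 measured V(D)J recombination genes reached 1.5-fold either way and their median was -0.04 (percentile 46.5), and just above 0 under the other 3 scalings. Of 25 B-lineage transcription factors, 0 reached 1.5-fold. ID3 (-0.54, -0.58 to -0.49) and XBP1 (-0.41, -0.45 to -0.37) were lower and IRF4 (0.48, 0.35 to 0.62) higher, and the median of 0.03 (-0.15 to 0.17) lay at percentile 99.3 of matched lists, but was -0.18 in cells called G1 only. Among 15 surface antigens of B-cell precursors CD99 was at least 1.5-fold higher, while SPN (-0.42) and CXCR4 (-0.33), the receptor that holds precursors in marrow, were lower; the list's median was -0.06 (percentile 37.8).

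Of the ETV6-RUNX1 leukemia signature only 4 genes were measured: RAG1 (0.53), the growth factor MDK (0.17, 0.14 to 0.20), SOCS2 (0.10, 0.01 to 0.18) and NRN1, which is outside the naming rule and is given to complete the list (0.03, -0.04 to 0.10). DDIT4L of the same list, just below the floor and named after its values were seen, was lower, at 2.96 against 9.73 CPM (-1.72, -2.01 to -1.43). Other members of this list below the floor are not given, so DDIT4L does not stand for them. Known RUNX1 target genes had a median of 0.02 (percentile 94.9) over 14 measured members, which ran from IGLL1 at -0.73 to ETV6 at 0.55. ETV6 was kept in this list, although it is part of the construct and reads of the construct may be counted for it. The 4 measured genes of mature B and plasma cells were IRF4 (0.48) and FCRLA (0.48) on the higher side and MZB1 (-0.46), of the antibody secretion pathway, and XBP1 (-0.41) on the lower side.

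MYC and ribosome biogenesis genes were lower by a small amount as a group. All 41 measured members had a log2 ratio below 0 (37 of 41 under each of the other 3 scalings), with a median of -0.13 (-0.17 to -0.10) at percentile 0 of 10000 matched lists; the median was -0.08 in cells called G1 only and -0.08 with totals without ribosomal protein and mitochondrial genes. MYC itself was at 104 against 135 CPM (-0.38, -0.43 to -0.32), C1QBP at -0.28 (-0.31 to -0.26) and NME2, which shares reads with the read-through gene, at -0.38 (-0.49 to -0.26). Cholesterol synthesis genes had a median of -0.16 (-0.25 to -0.07, percentile 0.160), with MSMO1 (-0.43), LSS (-0.33) and FDFT1 (-0.30) furthest from 0. In cells called G1 only the median was -0.067 and FDFT1 was at 0.019 (-0.19 to 0.23). Glycolysis and hypoxia genes had a median of -0.11 (-0.14 to -0.02, percentile 0.870), with PGK1 (-0.27), ALDOC (-0.24) and P4HA1 (-0.18) furthest from 0. FDFT1 and ALDOC were also markers of the subpopulation described below. In each of these 3 lists 0 members reached 1.5-fold.

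MHC class II genes, which present antigen to helper T cells, were the list with the highest median, 0.17 (-0.01 to 0.41), at percentile 100 of matched lists and with 11 of 14 members above 0. HLA-DMB (0.51, 0.38 to 0.65) and HLA-DMA (0.41, 0.32 to 0.49), which load peptides, and their activator CIITA (0.47, 0.27 to 0.68) were furthest from 0, and 0 members reached 1.5-fold. Of 15 genes of MHC class I and antigen processing, the immunoproteasome subunit PSMB10 was past 1.5-fold (-0.65, -0.78 to -0.53); PSMB8 was at -0.45 and TAP2 at -0.24, while the median was -0.04 (percentile 56.2), on either side of 0 depending on the scaling. Interferon-stimulated genes had a median of -0.17 (-0.24 to 0.10, percentile 0.0900), with BST2 at -0.40 and IFI6 at -0.27 but IFIT3 at 0.35.

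**Figure D3:**
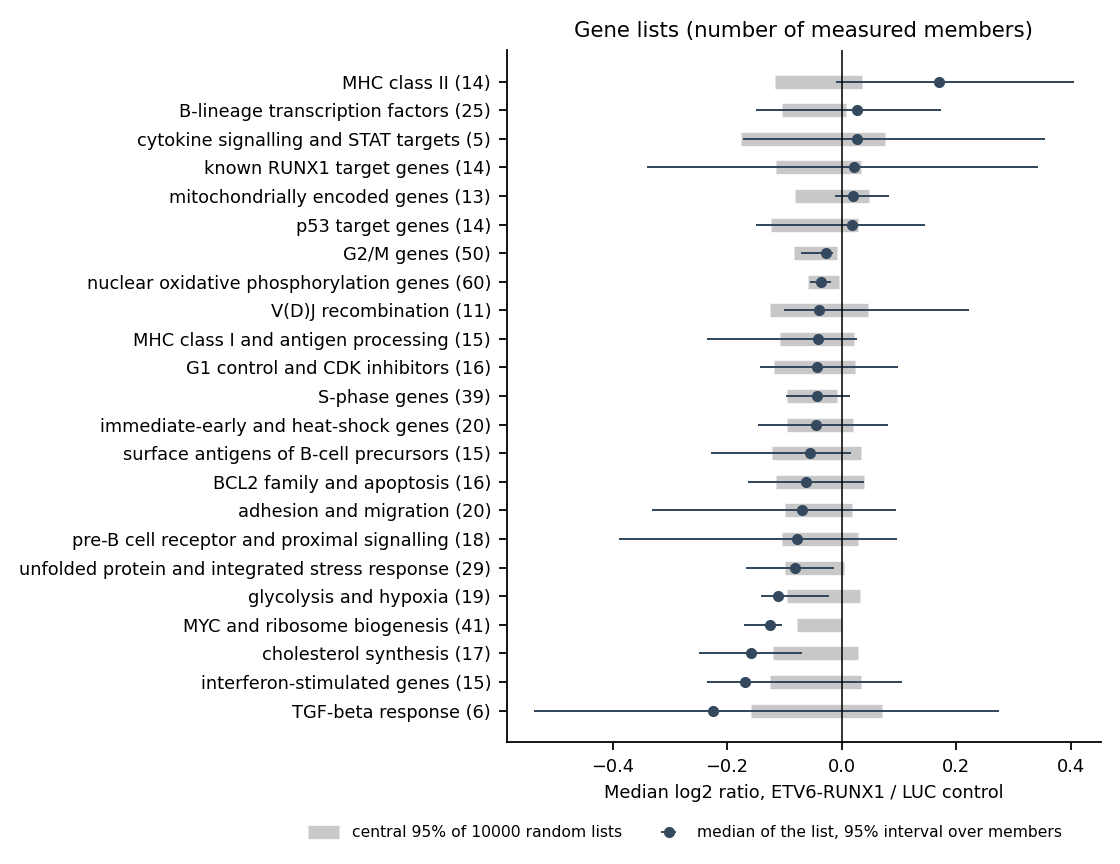
Median log2 ratio of ETV6-RUNX1 over LUC control (horizontal axis) for the lists with at least 5 measured members, with bars for the 95% interval over members and grey bands for the central 95% of 10000 random lists matched on expression. MHC class II and, by less, B-lineage transcription factors lie above their bands, and MYC and ribosome biogenesis (-0.13), cholesterol synthesis, interferon-stimulated, glycolysis and TGF-beta response genes lie below theirs.

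The integrin gene ITGA4 was at -0.61 (-0.78 to -0.43), the 1 of 20 adhesion and migration genes past 1.5-fold, but short of it in thinned cells (-0.41), with phases matched (-0.56), under the stricter cell filter (-0.56) and under the other 3 scalings; RAC2 (-0.50) and ICAM2 (-0.39) were also lower, and the median was -0.07 (percentile 15.7). The TGF-beta response list rested on 6 genes with a median of -0.22 (-0.54 to 0.27, percentile 0.120), led by ID3 (-0.54), ID2 (-0.41) and TGFB1 (-0.32). In cells called G1 only the median was -0.12 and ID2 was at 0.30 (-0.21 to 0.81). Of 5 cytokine signalling genes, JAK1 was at 0.36, PIM3 at -0.17 and IL7R at -0.11 (median 0.03, percentile 88.9). Among 16 genes of the BCL2 family and apoptosis, BCL2L1, which encodes a survival protein, was at 0.42 (0.26 to 0.59), BIK at -0.31 and BAX at -0.26 (median -0.06, percentile 24.1). In cells called G1 only BAX was at 0.035 (-0.16 to 0.23) and the median at 0.040. The 14 p53 target genes had a median of 0.02 (percentile 95.7), with FDXR at -0.27, BAX at -0.26 and MDM2 at 0.20. For 29 genes of the unfolded protein and integrated stress response the median was -0.08 (percentile 8.89), with XBP1 (-0.41), SEL1L (-0.33, but -0.11 under the stricter cell filter) and ATF5 (0.37, 0.34 to 0.41) furthest from 0. Immediate-early and heat-shock genes included ZFP36 (-0.52), IER2 (-0.38) and HSPA8 (-0.28), with a median over 20 members of -0.04 (percentile 39.7), on either side of 0 depending on the scaling. The 60 nuclear oxidative phosphorylation genes had a median of -0.04 (percentile 38.4), which turned to 0.01 with median-of-ratios scaling; NDUFC1 (-0.22), NDUFC2 (-0.21) and NDUFA13 (0.19) were furthest from 0. The 13 mitochondrially encoded genes had a median of 0.02 (percentile 81.9), with MT-ND3 at -0.24, MT-ATP6 at 0.10 and MT-CYB at 0.09.

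The cell cycle differed little between the libraries. In thinned cells, 18.5% of ETV6-RUNX1 cells (16.8 to 20.2) and 16.0% of control cells (14.3 to 17.7) were called G1, a difference of 2.496 percentage points (0.0602 to 4.92). Cells called S were 34.9% and 38.0%, and cells called G2/M 46.6% and 46.1%, with intervals of the differences that include 0. Without thinning, G1 shares were 16.7% and 13.1%. About as many cells in each library, 17.8% and 17.7%, lay within 0.05 of the score cut, the level of the calls moved with the settings, and free RNA was not estimated, so the calls give a comparison and not a measure of cycling. The 39 measured S-phase genes had a median of -0.04 (percentile 67.0), on either side of 0 depending on the scaling, with RFC2 (-0.41), TIPIN (-0.34) and RPA2 (-0.25) furthest from 0; in cells called G1 only the median was -0.27. The 50 G2/M genes had a median of -0.03 (percentile 82.0), above 0 under the other 3 scalings. NEK2 (-0.31), CDK1 (-0.28) and CDC20 (-0.21) were furthest from 0. In cells called G1 only the median of G2/M genes was -0.24. Cells are called G1 by low scores of the S-phase and G2/M lists themselves, so the medians of these lists there depend on that selection. Among 16 genes of G1 control, CDKN2D (-0.44) and MYC (-0.38) were lower and E2F1 (0.30, 0.22 to 0.38) higher. E2F1 was at -0.23 (-0.49 to 0.03) in cells called G1 only. The median of these 16 genes was -0.04 (percentile 58.9), on either side of 0 depending on the scaling.

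Ratios within called phases kept their sign for each of the 12 lowest and the 11 highest genes. For the 12 lowest, the median log2 ratio was -1.36 in cells called G1, -1.31 in S and -0.87 in G2/M, and for 11 of the 12 the ratio was closest to 0 in G2/M. LAT2 had log2 ratios of -3.23, -2.31 and -1.45 in G1, S and G2/M, FAM129C of -1.85, -1.77 and -0.90, and IGLL1 of -0.93, -1.08 and -0.52. The difference between phases was not tested.

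**Figure D4:**
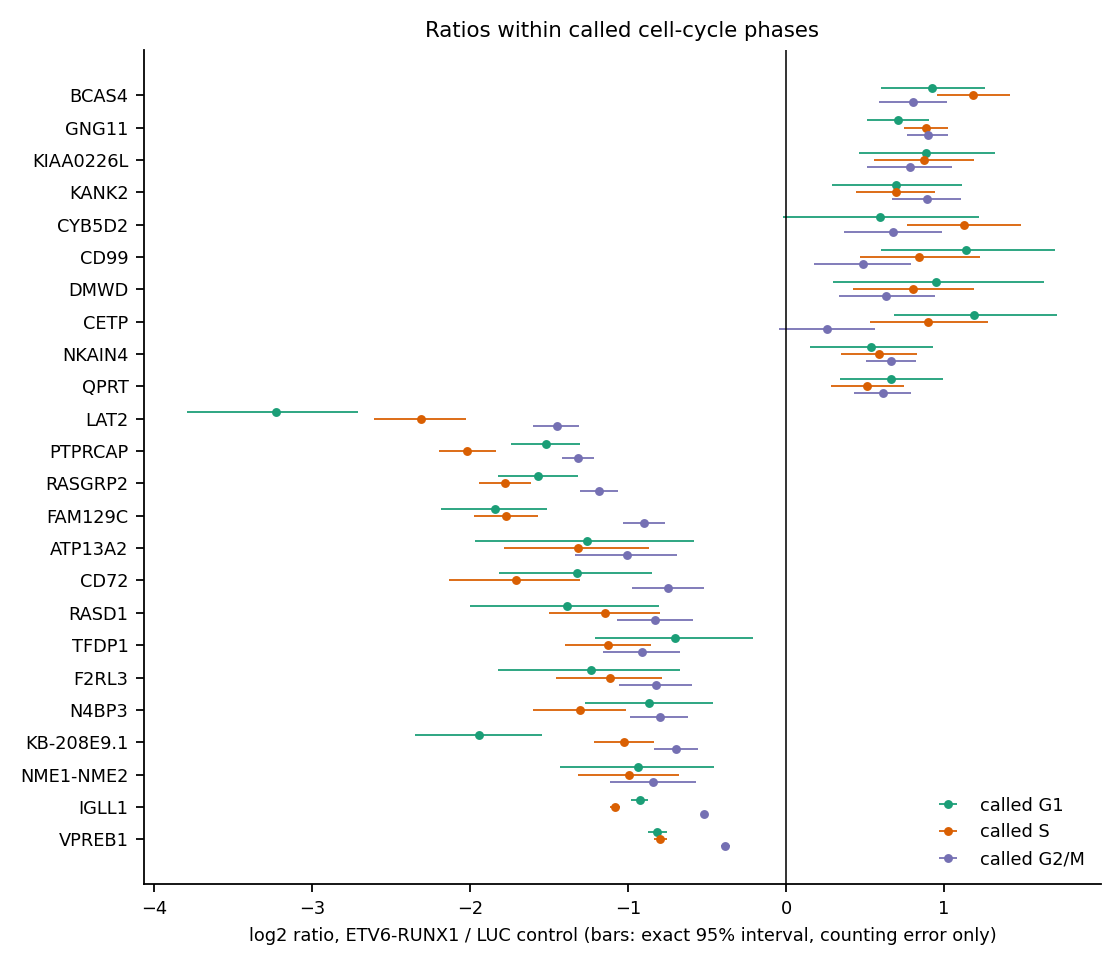
Log2 ratio of ETV6-RUNX1 over LUC control (horizontal axis) in cells called G1, S and G2/M for 10 of the highest genes, the 12 lowest genes, IGLL1 and VPREB1, with bars for exact 95% intervals (counting error only). The points of each gene lie on the same side of 0, and for LAT2 they run from -3.23 in G1 to -1.45 in G2/M.

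No cells of another type were found. None of the 5 clusters had a marker of T and NK, myeloid, erythroid and megakaryocyte, stem and progenitor, mature B and plasma, or epithelial and fibroblast cells among its top 10 genes, and CD79B, VPREB1 and IGLL1 were expressed in each cluster. Of the T and NK and the erythroid and megakaryocyte markers 0 were measured. The myeloid list had CST3 (11.5 and 10.1 CPM, log2 ratio 0.19), the stem and progenitor list EGFL7 (-0.25) and the epithelial and fibroblast list PDGFRA (68.1 and 66.4 CPM, 0.04, -0.04 to 0.11), which was at -0.51 (-0.72 to -0.31) in cells called G1 and at -0.091 with phases matched.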

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

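The GC adjustments and another set of subpopulation markers were chosen after the data were seen; the other alternatives were planned. Genes higher with ETV6-RUNX1 numbered 11 in the report and 17 with median-of-ratios scaling, 17 with TMM scaling, 17 with totals without ribosomal protein and mitochondrial genes, 18 with cells weighted equally, 23 in thinned cells, 76 in cells called G1 only, 139 at a floor of 1 CPM, 1 at 50 CPM, 0 at 2-fold and 98 at a log2 ratio of 0.32. Genes lower numbered 39 in the report and 161 in cells called G1 only, 232 at a floor of 1 CPM, 10 at 50 CPM, 5 at 2-fold and 197 at a log2 ratio of -0.32 or less. Other settings stayed within 1.5 times. The 11 higher genes were all shared with those found under the 3 other scalings, of the 39 lower genes 32 were, and with thinned cells 9 and 34 were shared (ATP13A2, at -1.16 there, was below the floor). The floors and sizes change the counts by construction; for the other settings the cause was not tested.

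Cells called G1 hold 6571184 and 5577487 UMIs, fewer than all cells, which widens counting error there; the cause of the moves was not tested further. In these cells the log2 ratio of ETV6 was -0.044 (-0.67 to 0.59) and of RUNX1 -0.31 (-0.60 to -0.02). E2F1 was at -0.23 (-0.49 to 0.03), BAX at 0.035 (-0.16 to 0.23), FDFT1 at 0.019 (-0.19 to 0.23) and ID2 at 0.30 (-0.21 to 0.81). All of these intervals but that of RUNX1 include 0, and that of ETV6 also holds its value over all cells. Medians in these cells were -0.27 for S-phase genes and -0.24 for G2/M genes, the lists whose low scores define the call. Other medians were -0.18 for B-lineage transcription factors, 0.040 for BCL2 family and apoptosis, -0.078 for MYC and ribosome biogenesis and -0.067 for cholesterol synthesis. The median of MYC and ribosome biogenesis genes was -0.083 with median-of-ratios scaling, -0.086 with TMM and -0.080 without ribosomal protein and mitochondrial genes. In that order of scalings G2/M genes turned to 0.015, 0.012 and 0.018, and nuclear oxidative phosphorylation genes to 0.0061, 0.0027 and 0.0089 and, with cells weighted equally, moved to -0.057. Mitochondrially encoded genes were at -0.024 with no cell filter. These moves follow from scaling shifts of 0.04, 0.04 and 0.05 or were not tested for a cause. Of the other 90 named genes, 48 moved outside their counting interval with the same sign in cells called G1 only and at most 14 under any other setting. PDGFRA (0.037, interval including 0) was at -0.51 in cells called G1 only, -0.091 phase-matched and just below 0 with cells weighted equally. Differences in phase shares stayed within their intervals under each alternative run. No paired analysis was possible because there is 1 library per group.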

Other observations

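The tests in this part were chosen after the results were seen, except the correlations outside the TFDP1 subpopulation and within clusters and the comparison of cells with and without an ETV6 UMI. Genes below were chosen after their values were seen where they fall outside the naming rule. Beyond the 12 lowest, the 39 genes at least 1.5-fold lower included the calcium-binding protein genes S100A4 (log2 ratio -0.85) and S100A6 (-0.83), the signalling inhibitor SPRY1 (-0.77), and MIF (-0.66, -0.69 to -0.63), which encodes a cytokine and was at 335 against 529 CPM. Also among the 39 were RGS19 (-0.64), the Rac exchange factor PREX1 (-0.63), STAP1 (-0.59), an adaptor of B cells, and CYFIP2 (-0.59). STAP1 and CYFIP2 were short of 1.5-fold under the other 3 scalings. STAP1 was also short of it with trends over GC content and length removed (-0.57), and CYFIP2 in thinned cells (-0.51) and with phases matched (-0.58). RPS17L (-0.76, but -0.55 in thinned cells) and HNRNPA1L2 (-0.68) also passed the size, but they have near-identical copies and are uncertain.

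The 39 lower genes had a median log2 ratio of -0.71 (-0.88 to -0.66). With trends over GC content and length removed it was -0.73 (-0.90 to -0.66), and with phases matched -0.79 (-0.94 to -0.72). In thinned cells it was -0.75 (-0.92 to -0.68) and under the stricter cell filter -0.75 (-0.93 to -0.67). These values argue against a smooth trend over whole-transcript GC content and length, phase mix and dying cells as the whole cause. Thinning could not decide on depth per cell, since ratios of scaled UMI sums hardly depend on it. A difference between the modified lines that was there before induction cannot be told apart from an effect of the fusion, since 0 of the libraries analysed were of uninduced cells. An effect of the fusion stays open as a hypothesis.

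The lowest genes varied together from cell to cell with ETV6-RUNX1. The mean pairwise correlation of the 12 lowest genes without TFDP1 was 0.0548 with ETV6-RUNX1 and 0.0136 in the control, a difference of 0.0411 against at most 0.0142 in 1000 matched gene sets, and over all lower genes but TFDP1 and NPY it was 0.0155 against at most 0.00406. Cells that differ in how far these genes are lowered would go with this, as a hypothesis. The matched sets held no gene past 1.5-fold and were matched on the mean of the libraries, so they do not show what other changed genes would give. Correlations were not computed under the stricter cell filter, so cell quality was not examined for them. A mixture of the TFDP1 subpopulation with other cells is argued against as the whole cause, since outside it the difference was 0.0352 against at most 0.0152, and so is a different spread over the clusters, since within clusters and phases it was 0.0387 against at most 0.0140. Cells with an ETV6 UMI did not stand out in the ETV6-RUNX1 library (log2 ratio of the summed genes 0.020, -0.06 to 0.10, against cells without), but the bound of -0.2 set beforehand was too loose, since ETV6 in the control was at 68.4% of its level with ETV6-RUNX1 and most of its UMIs need not come from the construct, so this cannot be told apart.

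TFDP1 was concentrated in a subpopulation of each library, which held 24.1% of ETV6-RUNX1 cells (22.3 to 25.9) and 31.1% of control cells (28.98 to 33.2). The neuropeptide gene NPY (-0.87, -0.99 to -0.75) was also higher there than outside (38.0 against 14.7 CPM with ETV6-RUNX1, 73.2 against 20.9 CPM in the control). The subpopulation was called from other genes, but these mark a cluster with TFDP1, the Y-linked gene EIF1AY and NPY among its top 10 genes. The concentration of TFDP1 and NPY was thus set in part by that choice. In the control library the marker GSTK1 was at 31.4 CPM in that cluster and 0.582 CPM in the main cluster. What sets these cells apart was not tested. Of the subpopulation's 15 markers, 4 (GSTK1, CYSTM1, ATPAF1 and MAP1B) were themselves over 1.5-fold lower between the libraries. With such markers left out the shares were 26.1% (24.3 to 27.9) and 32.3% (30.2 to 34.5). FDFT1 and ALDOC, lower in the lists above, and SOCS2, slightly higher, were also among the 15 markers. How far the share of these cells enters their ratios was not tested. The TFDP1 log2 ratio was -0.94 over all cells, -0.46 (-0.64 to -0.28) within the subpopulation, -1.37 (-1.85 to -0.90) outside it, -0.55 at equal shares and -0.20 (-0.41 to 0.02) in the cluster that TFDP1 leads. With the other markers it was -0.59 (-0.77 to -0.41) within. How much of it a smaller share accounts for cannot be told apart. Each interval within the called subpopulation spans 1.5-fold, while that of the cluster includes 0, and 31.6% and 28.4% of cells had an uncertain call. The TFDP1 ratio outside rests on 55 UMIs with ETV6-RUNX1 and 125 in the control. For NPY the ratio within was -0.94 (-1.13 to -0.76), and -0.88 (-1.06 to -0.71) with the other markers. Outside it was -0.51 (-0.68 to -0.34), short of 1.5-fold, and at equal shares -0.76 against -0.87 over all cells. The ratios within would argue against a smaller share as the whole cause for NPY if the called cells were equally pure in each library. That was not tested. Within the call, markers were also lower with ETV6-RUNX1. CYSTM1 was at 17.6 against 23.2 CPM and ATPAF1 at 13.7 against 20.9 CPM. NPY was lower by more, at 38.0 against 73.2 CPM, but what a less pure call adds cannot be told apart.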
